A study of Homo sapiens with 8 samples.

How the data were processed

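The 8 libraries came from cells labelled as 143B osteosarcoma cells stably expressing a control shRNA or an shRNA against ZDHHC8, treated with vehicle or cisplatin for 48 h, with 2 libraries per group labelled as biological replicates. Per the labels' protocols, RNA was extracted with TRIzol, treated with DNase I and enriched by poly(A) selection before library construction, the vehicle was PBS, and every library carries batch 1. The labels give no cisplatin dose, and the strandedness of the libraries is not stated in the sources used here, so values of genes that overlap another gene on either strand, and of near-identical paralogs, are uncertain. The authors deposited 1 table of normalized gene values for all 8 libraries on hg38, per the labels. The unit is not named in that table, and the deposited values were taken as FPKM. They are not whole numbers, the columns sum to different totals between 361060 and 391016, and abundant mitochondrial and ribosomal protein genes are present. The aligner, the quantifier and the annotation release are not given in the sources used here. Gene names, identifiers and coordinates are those of the deposited table.

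The plan made before the data were examined was for a count-based test, with limma if the table held no counts. Because the values are FPKM, limma was used and the planned count-based tests and normalizations were not run. Values were taken as deposited, without further scaling, and transformed to log2(FPKM + 1). Genes with at least 1 FPKM in at least 2 of the 8 libraries were tested, 13495 of 21123, and 402 genes were 0 in every library. With limma 3.58.1 in R 4.3.3, 1 model with a mean for each of the 4 groups was fitted by lmFit to all 8 libraries, followed by eBayes with an intensity trend (residual degrees of freedom 4, prior degrees of freedom 4.64). The 5 contrasts were cisplatin against vehicle in shControl and in shZDHHC8 cells, shZDHHC8 against shControl in vehicle and under cisplatin, and the interaction. P-values were adjusted by Benjamini-Hochberg over the tested genes of each contrast, and genes with an adjusted p below 0.05 were called higher or lower. The median SE of a log2 change was 0.079, and 0.11 for the interaction. P-values measure the spread between libraries labelled as biological replicates, which may hold technical variation alone if the cultures were not grown apart.

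The read depth cannot be had from FPKM. A search for the value of a whole read among 1444 lowly expressed long non-coding genes found no shared step, since the most common ratio between replicates was shared by 4 genes. The precision was therefore taken from replicates. The method was tested on simulated data in which 200 of 13495 genes carried a known change over the observed spread: with a log2 change of 1, 90% were recovered for cisplatin in shControl cells, 94% for the knockdown in vehicle, 100% for cisplatin in shZDHHC8 cells, 94% for the knockdown under cisplatin and 80% for the interaction. With a log2 change of 0.5 the shares were 52%, 70%, 64%, 74% and 36%, and with 0.25 they were 16%, 14%, 12%, 16% and 0%. Of the calls over all sizes of change together, 5.84%, 2.80%, 3.50%, 7.79% and 6.19% were false. The changed genes were drawn from those with a mean log2 value above 1, and the noise was normal. In the data 30.4% to 62.2% of genes were called, far more than were changed in the simulation, so these shares do not carry over to the data.

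The 26 gene lists, with 951 members of which 902 matched a gene in the table and 799 were tested, were written from general knowledge before the data were examined. They were tested with camera of limma with the preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 26 lists of each contrast. Camera compares the members with all other genes, so a list can pass as lower while its median is above 0. The alternatives were camera with a correlation estimated from the data and fry, which asks whether the members move on balance in a common direction. Genes were also adjusted over each list alone. The genes named in the text follow a rule written before the data were examined: ZDHHC8 and CTNNB1; in each contrast the 8 largest rises and 8 largest falls among genes called, changed the same way in every pair of libraries and at 1 FPKM or more in a group compared; and up to 4 called members with the smallest p of each list that passed and of the WNT target, palmitoylation and p53 lists. Genes named outside that rule were chosen after their values were seen, which is said where they appear; the second pair of values given for TRIB3 and CXCL1 with the interaction is of that kind.

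The alternatives chosen before the data were examined were a pseudocount of 0.1, no filter on low values, eBayes without a trend, a fit of the 4 libraries of a comparison alone, a block for replicate number, a threshold of 1 on the absolute log2 change, each library left out in turn, and the WNT target list without members shared with other lists. The list shares no member with another list, so this last alternative left it as it was and tests nothing. Scaling to a common column total, median-of-ratios scaling and a mean of at least 10 FPKM were added after the data had been seen. Scaling matters here because the median log2 change of all tested genes was 0.070 for cisplatin in shControl cells and 0.13 in shZDHHC8 cells, and -0.030 and -0.0036 after median-of-ratios scaling. Agreement of comparisons was measured by Pearson's r and Spearman's rho across genes only where the comparisons share no library. For the closing section, gene span came from the coordinates of the deposited table, and transcript length and GC content from GENCODE release 29.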

Results

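Poly(A)-selected RNA from cells labelled 143B, a human osteosarcoma line, was sequenced in a 2 × 2 design. Cells stably carried a control shRNA (shControl) or an shRNA against ZDHHC8 (shZDHHC8) and received vehicle or cisplatin, a platinum drug that crosslinks DNA, for 48 h. Each of the 4 groups had 2 libraries, labelled as biological replicates, and the table listed 21123 genes, of which 14719 were protein-coding, 4561 long non-coding and 1843 pseudogenes. Values were FPKM, so the read depth behind each value is unknown, and the column totals lay between 361060 and 391016. Pearson's r of log2 values across the 13495 tested genes was 0.995 to 0.996 within groups and 0.939 to 0.978 between groups. Levels below are mean FPKM ± SD (n = 2 libraries), and log2 changes are differences of mean log2(FPKM + 1) from limma, a scale that understates the change of low genes. P-values measure the spread between the labelled replicates. For each gene list the counts of tested members called higher and lower are given, followed in parentheses by the counts adjusted over the list alone. The camera adjusted p of a list is followed by that with an estimated correlation. The series title names ZDHHC8, a palmitoyltransferase, and beta-catenin, the WNT pathway's transcriptional co-activator encoded by CTNNB1. Both genes and a list of WNT target genes are therefore given in each comparison. Of the 44 members of that list, 34 matched a listed gene and 23 were tested. The untested members are not part of any result for the list.

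ZDHHC8 (ENSG00000099904, chromosome 22, positions 20129456 to 20148007 of hg38) was at 23.4 ± 0.386 FPKM in shControl cells with vehicle and 12.1 ± 3.19 in shZDHHC8 cells with vehicle, a log2 change of -0.92 ± 0.13 (SE) (limma adjusted p = 0.000472). Under cisplatin the levels were 32.6 ± 0.37 and 22.9 ± 0.831 FPKM, a log2 change of -0.49 ± 0.13 (SE) (limma adjusted p = 0.0102). Every shZDHHC8 library lay below every shControl library of the same treatment. ZDHHC8 rose with cisplatin in both backgrounds, by 0.46 in shControl and 0.89 in shZDHHC8 cells, so that the level in shZDHHC8 cells under cisplatin was near that of untreated shControl cells. The rise in shControl cells lost its call under median-of-ratios scaling (limma adjusted p = 0.0556) and without replicate 2 of vehicle or of cisplatin (adjusted p = 0.0578 and 0.0517). The knockdown under cisplatin lost it without shZDHHC8 cisplatin replicate 2 (adjusted p = 0.0558). The vehicle libraries of the knockdown differed from each other, at 14.3 and 9.81 FPKM. CTNNB1 (ENSG00000168036, chromosome 3, positions 41194741 to 41260096) was at 57.9 ± 0.0625 and 52.7 ± 1.44 FPKM with vehicle and at 41.3 ± 0.158 and 47.9 ± 2.08 FPKM with cisplatin, in shControl and shZDHHC8 cells respectively. It fell with cisplatin in shControl cells by 0.48 on the log2 scale (limma adjusted p = 3.94e-05). The knockdown changed it by -0.13 in vehicle (limma adjusted p = 0.0456), a call that ended with any of the 8 libraries left out, at -0.16 to -0.11. That call also ended with a replicate block (limma adjusted p = 0.0591), eBayes without a trend (adjusted p = 0.0893) and a fit of the 4 libraries alone (adjusted p = 0.073). Under cisplatin CTNNB1 was changed by 0.21 (limma adjusted p = 0.0048), and by 0.12 after scaling to a common total, which did not pass (adjusted p = 0.0646).

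**Figure D1:**
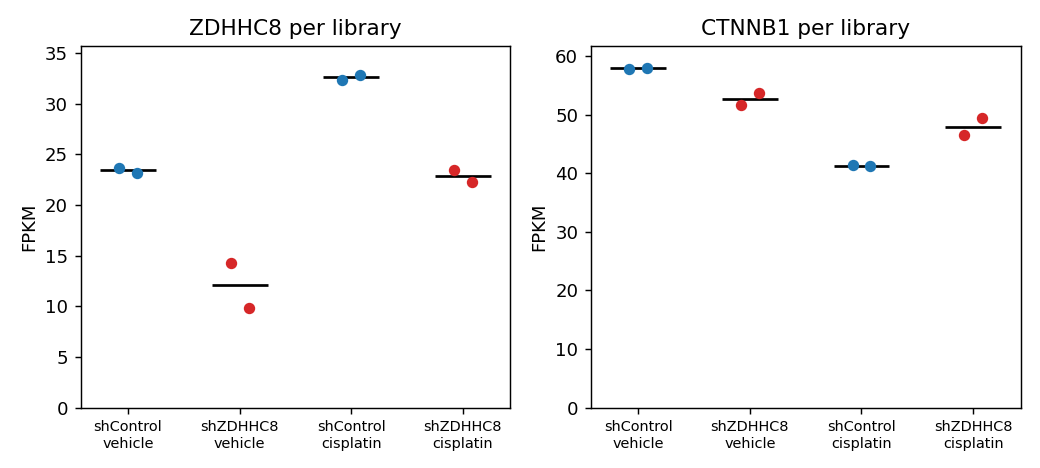
FPKM of ZDHHC8 and CTNNB1 in each of the 8 libraries, by group. Points are libraries and horizontal lines are group means of 2 libraries. ZDHHC8 lay at 9.81 and 14.3 FPKM in shZDHHC8 cells with vehicle and at 23.1 and 23.7 in shControl cells with vehicle.

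The effect of cisplatin in shControl cells shows the drug response of cells with the control shRNA. GADD45A (ENSG00000116717, chromosome 1, positions 67685201 to 67688334), a p53-regulated growth arrest gene, went from 91.9 ± 0.916 to 798 ± 12.5 FPKM, a log2 change of 3.10 ± 0.04 (SE) (limma adjusted p = 1.68e-09). CDKN1A, the cyclin-dependent kinase inhibitor p21, went from 4.04 ± 0.0224 to 15.9 ± 0.373 FPKM. AEN, a p53-induced nuclease, went from 4.19 ± 0.307 to 28.2 ± 0.73. Inflammatory cytokines rose as well. IL6 (ENSG00000136244, chromosome 7, positions 22725884 to 22732002), which overlaps a gene on the opposite strand, went from 15.6 ± 0.0947 to 97.5 ± 1.94 FPKM, and the chemokine CXCL8 from 33.0 ± 1.26 to 233 ± 13.5. CCL20 went from 0.936 ± 0.336 to 17.4 ± 0.796. Among the steepest falls were VAV3, from 9.61 ± 0.514 to 0.208 ± 0.0272 FPKM, and the keratin KRT5, from 73.5 ± 0.701 to 10.2 ± 0.227. Each of these changes had the same direction in all 4 pairs of a treated and an untreated library. For genes named as the largest rises and falls this was a condition of being named, so it adds no support for them.

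By list, NF-kB and secretory inflammation genes rose, with 19 of 23 higher and 3 lower (19 and 3 alone) and a median log2 change of 1.60 (camera adjusted p = 1.47e-05, p = 0.136 with estimated correlation). ATF4 and integrated stress response targets had 24 of 32 higher and 4 lower (25 and 5 alone; camera adjusted p = 3.64e-05, p = 0.104 with estimated correlation). TRIB3, an ATF4-induced pseudokinase, rose by 2.04 and PPP1R15A, a phosphatase subunit that restores translation, by 2.56. Immediate-early and AP-1 genes had 21 of 28 higher and 3 lower (21 and 3 alone), among the former the MAP kinase phosphatases DUSP5, DUSP4 and DUSP1 (camera adjusted p = 5.18e-05, p = 0.136 with estimated correlation). Crosslink and homologous recombination repair genes had 29 of 39 higher and 3 lower (29 and 3 alone), among them BRCA1 (0.98), BRCA2 (1.01) and XRCC3 (1.52; camera adjusted p = 0.000751, p = 0.158 with estimated correlation). DNA replication and E2F genes had 25 of 36 higher and 3 lower (25 and 3 alone; camera adjusted p = 0.000531, p = 0.136 with estimated correlation), with the licensing factors CDC6 and ORC6 up by 1.25 and 1.14 while MCM6 went from 24.2 ± 0.328 to 11.2 ± 0.216 FPKM. Cytosolic ribosomal proteins had 33 of 68 higher and 4 lower (32 and 3 alone; camera adjusted p = 0.0249, p = 0.62 with estimated correlation).

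Cholesterol synthesis genes fell, with 1 of 29 higher and 25 lower (1 and 25 alone) and a median of -0.73 (camera adjusted p = 3.07e-10, p = 0.104 with estimated correlation). The stearoyl-CoA desaturase SCD went from 31.4 ± 0.923 to 9.46 ± 0.0337 FPKM. G2/M and mitosis genes had 4 of 38 higher and 22 lower (4 and 25 alone; camera adjusted p = 3.64e-05, p = 0.358 with estimated correlation), including the kinesin KIF20A (-1.47) and the kinase PLK1 (-1.13), against a rise of KIF2C (0.73). NRF2 and oxidative stress targets had 4 of 29 higher and 22 lower (4 and 22 alone; camera adjusted p = 5.42e-06, p = 0.136 with estimated correlation), with the aldo-keto reductases AKR1C1 and AKR1C3 at -1.51 and -1.63. Glycolysis and hypoxia genes had 3 of 32 higher and 19 lower (3 and 19 alone; camera adjusted p = 8.3e-05, p = 0.136 with estimated correlation), although ADM and ANGPTL4 in that list rose by 1.72 and 1.70. Extracellular matrix and mesenchymal genes had 7 of 37 higher and 21 lower (7 and 21 alone; camera adjusted p = 0.000531, p = 0.104 with estimated correlation). Interferon-stimulated genes had 2 of 33 higher and 15 lower (2 and 15 alone; camera adjusted p = 0.000724, p = 0.222 with estimated correlation). Unfolded protein response genes had 6 of 29 higher and 12 lower (6 and 12 alone; camera adjusted p = 0.0314, p = 0.456 with estimated correlation). Mitochondrially encoded transcripts had 0 of 13 higher and 9 lower (0 and 9 alone; camera adjusted p = 0.000805, p = 0.329 with estimated correlation).

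The WNT/beta-catenin target list was split, with 11 of 23 higher and 8 lower (11 and 8 alone) and a median of 0.13 (camera adjusted p = 0.783, p = 0.798 with estimated correlation). That median was 0.061 without shControl vehicle replicate 1, 0.20 without replicate 2, 0.16 and 0.082 without shControl cisplatin replicates 1 and 2, and 0.066 under median-of-ratios scaling, and it passed in none of these. CCND1, the cyclin D1 gene, went from 47.2 ± 0.704 to 107 ± 1.17 FPKM, MYC from 33.5 ± 0.333 to 80.2 ± 4.75 and the WNT antagonist DKK1 from 38.5 ± 2.48 to 105 ± 0.844. The p53 target list did not pass (18 of 35 higher and 8 lower, 19 and 8 alone; camera adjusted p = 0.182, p = 0.358 with estimated correlation), nor did nucleotide excision repair (18 of 33 higher and 5 lower, 18 and 6 alone; camera adjusted p = 0.199, p = 0.621 with estimated correlation). Apoptosis regulators had 17 of 33 higher and 6 lower (18 and 6 alone; camera adjusted p = 0.292, p = 0.602 with estimated correlation). Osteoblast lineage genes had 3 of 14 higher and 6 lower (3 and 6 alone; camera adjusted p = 0.15, p = 0.318 with estimated correlation). In limma, 4967 genes were higher and 3421 lower of 13495, of which 465 and 270 changed by at least 1 on the log2 scale. Median-of-ratios scaling turned the split to 3929 higher and 4496 lower and ended the call of the ribosomal proteins (camera adjusted p = 0.243).

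The effect of the knockdown in vehicle shows how shZDHHC8 cells differed from shControl cells without drug. TM4SF19, a tetraspan membrane protein (ENSG00000145107, chromosome 3, positions 196319342 to 196338503), rose from 1.56 ± 0.0833 to 43.9 ± 3.10 FPKM (log2 change 4.13 ± 0.063 (SE), limma adjusted p = 8.37e-09). It overlaps a readthrough gene on its strand. The secreted lipoprotein lipase inhibitor ANGPTL4 rose from 1.87 ± 0.0534 to 21.2 ± 0.676 FPKM and the nuclear body protein SP140 from 0.752 ± 0.031 to 10.9 ± 0.111. EGR1, an immediate-early transcription factor, fell from 28.9 ± 1.15 to 2.06 ± 0.128 FPKM, and the tryptophan-degrading enzyme IDO1 from 19.4 ± 0.049 to 1.44 ± 0.367. IL6 fell from 15.6 ± 0.0947 to 1.88 ± 0.335 and KRT17 from 27.1 ± 0.314 to 3.04 ± 0.102. The paralogous palmitoyltransferase ZDHHC18 (ENSG00000204160, chromosome 1, positions 26826688 to 26857604) fell from 13.2 ± 0.181 to 5.31 ± 0.0473 FPKM, a log2 change of -1.17 ± 0.058 (SE) (limma adjusted p = 1.76e-06), and ZDHHC7 from 32.8 ± 0.395 to 18.1 ± 0.491. The list of palmitoylation enzymes as a whole did not pass, with 7 of 29 higher and 6 lower (7 and 6 alone; camera adjusted p = 0.969, p = 0.987 with estimated correlation).

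Mitosis genes were lower in the knockdown, with 0 of 38 higher and 33 lower (1 and 34 alone) and a median of -0.43 (camera adjusted p = 1.69e-11, p = 0.258 with estimated correlation). The proliferation marker MKI67 went from 46.7 ± 2.40 to 24.3 ± 0.49 FPKM. DNA replication and E2F genes had 4 of 36 higher and 18 lower (4 and 18 alone; camera adjusted p = 0.00823, p = 0.258 with estimated correlation), with thymidine kinase TK1 at -0.99. NF-kB and secretory inflammation genes had 4 of 23 higher and 15 lower (4 and 16 alone; camera adjusted p = 0.00013, p = 0.258 with estimated correlation). CXCL1 went from 145 ± 0.98 to 33.8 ± 0.066 FPKM, whereas IL1A rose from 10.3 ± 0.387 to 34.4 ± 1.22. Cholesterol synthesis genes had 2 of 29 higher and 24 lower (2 and 25 alone; camera adjusted p = 2.48e-08, p = 0.0713 with estimated correlation), including SREBF2, the sterol-responsive transcription factor gene, at -1.05 and SCD at -1.87. WNT pathway components had 4 of 36 higher and 15 lower (4 and 15 alone; camera adjusted p = 0.0251, p = 0.264 with estimated correlation), among them PORCN, which acylates WNT ligands, at -1.12 and the receptor FZD2 at -0.79. The WNT target list did not pass, with 5 of 23 higher and 9 lower (7 and 9 alone) and a median of -0.11 (camera adjusted p = 0.245, p = 0.364 with estimated correlation). CCND1 rose from 47.2 ± 0.704 to 90.2 ± 1.01 FPKM while MMP7 and SOX4 fell by 1.78 and 0.63 on the log2 scale.

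Other lists rose with the knockdown. Cytosolic ribosomal proteins had 57 of 68 higher and 1 lower (60 and 1 alone; camera adjusted p = 4.3e-12, p = 0.258 with estimated correlation). Nuclear genes of oxidative phosphorylation had 29 of 43 higher and 4 lower (30 and 4 alone; camera adjusted p = 2.3e-05, p = 0.258 with estimated correlation). NRF2 and oxidative stress targets had 25 of 29 higher and 1 lower (25 and 1 alone; camera adjusted p = 5.44e-08, p = 0.161 with estimated correlation), with TXNRD1, thioredoxin reductase, going from 73.6 ± 2.07 to 189 ± 9.53 FPKM. ATF4 and integrated stress response targets had 22 of 32 higher and 3 lower (22 and 3 alone) and a median of 0.56 (camera adjusted p = 9.42e-07, p = 0.0713 with estimated correlation), with TRIB3 at 1.15 and PHGDH, of serine synthesis, at 1.08. Lysosome and autophagy genes had 22 of 31 higher and 3 lower (22 and 3 alone; camera adjusted p = 1.47e-05, p = 0.0713 with estimated correlation), with prosaposin, PSAP, going from 356 ± 4.55 to 765 ± 1.88 FPKM. Glycolysis and hypoxia genes had 17 of 32 higher and 2 lower (17 and 2 alone; camera adjusted p = 0.0015, p = 0.258 with estimated correlation). In limma 3602 genes were higher and 3373 lower, 180 and 220 of them by at least 1 on the log2 scale. Scaling to a common total gave 2897 higher and 4051 lower, and median-of-ratios scaling 3448 and 3617. Mitochondrially encoded transcripts did not rise, with 2 of 13 higher and 7 lower (2 and 7 alone) and a median of -0.18. They did not pass as deposited (camera adjusted p = 0.0673, p = 0.512 with estimated correlation) but passed as lower after scaling to a common total (camera adjusted p = 0.0311). The readthrough gene NDUFC2-KCTD14 (log2 change 2.70) shares its strand with both parent genes and lost its call without shControl vehicle replicate 2 or either shZDHHC8 vehicle replicate (limma adjusted p = 0.0669, 0.05003 and 0.0676).

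The effect of cisplatin in shZDHHC8 cells shows the drug response after the knockdown. Under median-of-ratios scaling the median change of all genes moved from 0.13 to -0.0036 on the log2 scale, so changes near 0.13 stand at the middle of all genes. The stress-induced transcription factor ATF3 rose from 5.46 ± 0.0141 to 28.8 ± 0.502 FPKM (log2 change 2.20 ± 0.053 (SE), limma adjusted p = 2.38e-07). The NF-kB inhibitor TNFAIP3 rose from 2.13 ± 0.011 to 12.9 ± 0.627 and the kinase SGK1 from 6.59 ± 0.322 to 23.5 ± 0.653. GADD45A rose from 105 ± 2.28 to 324 ± 1.59 FPKM and CDKN1A from 3.44 ± 0.162 to 10.2 ± 0.36. The steepest falls included GMDS, of GDP-fucose synthesis, from 17.9 ± 1.65 to 4.16 ± 0.0246 FPKM, and the receptor phosphatase PTPRM, from 17.3 ± 0.756 to 4.40 ± 0.155. The syntaxin STX8 fell from 11.1 ± 0.0122 to 2.52 ± 0.253 and LTBP1, which binds latent TGF-beta, from 5.62 ± 0.195 to 1.17 ± 0.0909. FN1, fibronectin, fell from 299 ± 7.47 to 124 ± 0.862 FPKM.

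The p53 target list rose in these cells, with 20 of 35 higher and 2 lower (20 and 2 alone) and a median of 0.30 (camera adjusted p = 0.0146, p = 0.189 with estimated correlation). The interaction did not pass for this list (8 of 35 higher and 7 lower, 11 and 8 alone; camera adjusted p = 0.745, p = 0.782 with estimated correlation). Immediate-early and AP-1 genes had 22 of 28 higher and 1 lower (23 and 1 alone; camera adjusted p = 0.000247, p = 0.151 with estimated correlation). Crosslink and homologous recombination repair genes had 18 of 39 higher and 0 lower (18 and 0 alone; camera adjusted p = 0.0263, p = 0.285 with estimated correlation). NF-kB and secretory inflammation genes had 13 of 23 higher and 4 lower (14 and 4 alone; camera adjusted p = 0.0274, p = 0.347 with estimated correlation). Replication-dependent histones had 16 of 23 higher and 0 lower (17 and 0 alone; camera adjusted p = 0.00755, p = 0.166 with estimated correlation), among them H2BC12, from 31.2 ± 4.66 to 62.0 ± 1.18 FPKM. These histone transcripts normally lack poly(A) tails, and the libraries were poly(A)-selected. Extracellular matrix and mesenchymal genes fell, with 7 of 37 higher and 21 lower (7 and 22 alone; camera adjusted p = 7.12e-09, p = 0.0503 with estimated correlation), against a rise of SNAI1 (1.67). NRF2 targets had 3 of 29 higher and 18 lower (3 and 18 alone; camera adjusted p = 3.74e-07, p = 0.151 with estimated correlation). Glycolysis and hypoxia genes had 5 of 32 higher and 15 lower (5 and 16 alone; camera adjusted p = 5.11e-06, p = 0.151 with estimated correlation). Ribosomal proteins had 2 of 68 higher and 30 lower (2 and 30 alone; camera adjusted p = 1.55e-09, p = 0.285 with estimated correlation). Osteoblast lineage genes had 1 of 14 higher and 7 lower (1 and 7 alone; camera adjusted p = 0.00247, p = 0.151 with estimated correlation). Cholesterol synthesis genes passed as lower with 4 of 29 higher and 10 lower (4 and 9 alone; camera adjusted p = 0.00755, p = 0.189 with estimated correlation). Platinum transport and detoxification genes had 4 of 24 higher and 9 lower (5 and 9 alone; camera adjusted p = 0.0199, p = 0.214 with estimated correlation), with metallothionein MT2A going from 791 ± 6.00 to 553 ± 0.00707 FPKM.

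G2/M genes passed as lower than other genes (7 of 38 higher and 11 lower, 7 and 11 alone; camera adjusted p = 0.0238, p = 0.601 with estimated correlation) although their median was 0.037, and -0.12 under median-of-ratios scaling. Unfolded protein response genes had 9 of 29 higher and 9 lower (9 and 11 alone; camera adjusted p = 0.0257, p = 0.483 with estimated correlation). Markers of other cell types passed as lower, with 1 of 9 higher and 4 lower (2 and 4 alone; camera adjusted p = 0.0146, p = 0.166 with estimated correlation). KRT5 changed by -1.62 on the log2 scale and KRT19 went from 77.3 ± 1.21 to 49.2 ± 2.32 FPKM, while CD68 rose from 43.6 ± 3.13 to 64.5 ± 5.98. KRT8, also in this list, was at 445 FPKM in shZDHHC8 cells with vehicle. The list thus holds genes that these cells express and does not measure the presence of other cells. The WNT target list had 7 of 23 higher and 4 lower (6 and 4 alone), a median of 0.0042, which was 0.0013 to 0.050 with a library left out, -0.0093 under common-total scaling and -0.14 under median-of-ratios scaling, and a camera direction of lower (camera adjusted p = 0.402, p = 0.508 with estimated correlation). CTNNB1 changed by -0.14 (limma adjusted p = 0.0432), a call that ended with any library other than shZDHHC8 cisplatin replicate 2 left out, at -0.16 to -0.092. That call also ended with a replicate block (limma adjusted p = 0.0563), eBayes without a trend (adjusted p = 0.085) and a fit of the 4 libraries alone (adjusted p = 0.0884). In limma 4976 genes were higher and 1841 lower, 132 and 69 of them by at least 1, and median-of-ratios scaling gave 2805 higher and 3163 lower.

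The effect of the knockdown under cisplatin shows how the treated cells of both backgrounds differed. Inflammatory genes were lower in shZDHHC8 cells. IL6 was at 97.5 ± 1.94 FPKM in shControl and 7.49 ± 0.382 in shZDHHC8 cells (log2 change -3.54 ± 0.08 (SE), limma adjusted p = 4.29e-08). CXCL1 (ENSG00000163739, chromosome 4, positions 73869393 to 73871308) was at 256 ± 8.41 and 24.1 ± 0.777, and CXCL8 at 233 ± 13.5 and 50.9 ± 4.14. The NF-kB and secretory inflammation list had 4 of 23 higher and 18 lower (4 and 18 alone) and a median of -1.47 (camera adjusted p = 5.67e-07, p = 0.151 with estimated correlation). TM4SF19, MILR1, SP140 and GPNMB, a lysosomal and melanosomal glycoprotein, were higher, GPNMB at 0.472 ± 0.0564 and 9.54 ± 0.551 FPKM. NRF2 targets were higher as a list, with 24 of 29 higher and 1 lower (25 and 1 alone; camera adjusted p = 5.67e-07, p = 0.151 with estimated correlation), and AKR1C1, AKR1C2 and AKR1C3, near-identical paralogs whose reads are hard to assign, differed by 2.42, 2.75 and 2.53. MMP2, a gelatinase, was higher by 2.24 on the log2 scale.

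The WNT target list was lower under cisplatin, with 4 of 23 higher and 11 lower (4 and 11 alone) and a median of -0.21 (camera adjusted p = 0.031, p = 0.181 with estimated correlation). MYC was at 80.2 ± 4.75 FPKM in shControl and 43.5 ± 2.13 in shZDHHC8 cells, CCND1 at 107 ± 1.17 and 75.5 ± 0.389, and CCN1, a matricellular protein gene, at 153 ± 1.38 and 79.4 ± 0.459. WNT pathway components were lower, with 4 of 36 higher and 17 lower (4 and 16 alone; camera adjusted p = 0.00706, p = 0.234 with estimated correlation), among them PORCN (-1.37) and the co-receptor LRP5 (-1.51). DNA replication and E2F genes had 7 of 36 higher and 24 lower (7 and 24 alone; camera adjusted p = 2.6e-05, p = 0.151 with estimated correlation). G2/M genes had 4 of 38 higher and 21 lower (4 and 21 alone; camera adjusted p = 0.00051, p = 0.449 with estimated correlation). Crosslink and homologous recombination repair genes had 3 of 39 higher and 15 lower (2 and 14 alone; camera adjusted p = 0.031, p = 0.298 with estimated correlation). Extracellular matrix genes had 10 of 37 higher and 21 lower (10 and 21 alone; camera adjusted p = 0.031, p = 0.181 with estimated correlation). Lysosome and autophagy genes were higher, with 22 of 31 higher and 3 lower (22 and 3 alone; camera adjusted p = 3.51e-05, p = 0.151 with estimated correlation). So were glycolysis and hypoxia genes, with 21 of 32 higher and 3 lower (21 and 3 alone; camera adjusted p = 0.000469, p = 0.181 with estimated correlation). Nuclear oxidative phosphorylation genes had 27 of 43 higher and 6 lower (27 and 6 alone; camera adjusted p = 0.0004, p = 0.298 with estimated correlation). Histones had 18 of 23 higher and 0 lower (18 and 1 alone; camera adjusted p = 0.0004, p = 0.151 with estimated correlation). Among palmitoyltransferases ZDHHC18 was at 21.3 ± 0.464 and 5.59 ± 0.237 FPKM, a log2 change of -1.76 ± 0.058 (SE) (limma adjusted p = 1.94e-07), while their list had 13 of 29 higher and 5 lower (13 and 5 alone; camera adjusted p = 0.362, p = 0.449 with estimated correlation).

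Immediate-early genes passed as lower (7 of 28 higher and 14 lower, 7 and 14 alone; camera adjusted p = 0.0493, p = 0.298 with estimated correlation) and mitochondrially encoded transcripts as higher (8 of 13 higher and 0 lower, 8 and 0 alone; camera adjusted p = 0.031, p = 0.471 with estimated correlation). Both lost their calls under scaling to a common total (camera adjusted p = 0.0562 and 0.0799), under which interferon-stimulated genes passed as higher (adjusted p = 0.0264, against 0.0508 as deposited). In limma 4561 genes were higher and 3720 lower, 371 and 231 of them by at least 1. Scaling to a common total turned the split to 3718 higher and 4613 lower, and median-of-ratios scaling to 4040 and 4224.

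The interaction, the cisplatin effect in shZDHHC8 minus that in shControl cells, tests whether the drug response differed between the backgrounds. It passed for 2298 genes with a more positive and 1806 with a more negative effect in shZDHHC8 cells, against 2139 and 2059 after scaling to a common total and 2061 and 2120 under median-of-ratios scaling. Of these 4104 genes, 1661 fell in shControl cells and had a more positive effect in shZDHHC8 cells, and 1589 rose in shControl cells and had a more negative effect. TRIB3 (ENSG00000101255, chromosome 20, positions 362835 to 397559) rose with cisplatin from 24.8 ± 0.722 to 105 ± 1.28 FPKM in shControl cells and went from 56.2 ± 1.57 to 69.9 ± 3.33 in shZDHHC8 cells, an interaction of -1.74 ± 0.072 (SE) (limma adjusted p = 8.31e-06). ATF4 and integrated stress response targets had a more negative effect, with 1 of 32 higher and 26 lower (1 and 27 alone) and a median of -0.56. In vehicle the list was higher in shZDHHC8 cells (camera adjusted p = 9.42e-07, p = 0.0713 with estimated correlation). Under cisplatin it had 12 of 32 higher and 13 lower (12 and 13 alone) between the backgrounds, with a median of 0.053 that turned to -0.042 after scaling to a common total and -0.0035 under median-of-ratios scaling (camera adjusted p = 0.515, p = 0.597 with estimated correlation). With cisplatin in shZDHHC8 cells it had 10 of 32 higher and 14 lower (10 and 14 alone; camera adjusted p = 0.0559, p = 0.214 with estimated correlation). In the interaction it was the only list in the 5 comparisons whose call held with both correlations (camera adjusted p = 6.98e-15, p = 0.0262 with estimated correlation).

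NF-kB genes had a more negative effect (3 of 23 higher and 17 lower, 3 and 17 alone; camera adjusted p = 3.85e-08, p = 0.136 with estimated correlation), as for CXCL1, which rose in shControl cells and was at 33.8 ± 0.066 and 24.1 ± 0.777 FPKM in shZDHHC8 cells. Ribosomal proteins went the same way (0 of 68 higher and 39 lower, 0 and 47 alone; camera adjusted p = 1.38e-13, p = 0.249 with estimated correlation). So did DNA replication genes (3 of 36 higher and 15 lower, 3 and 17 alone; camera adjusted p = 0.000637, p = 0.156 with estimated correlation) and repair genes (2 of 39 higher and 5 lower, 1 and 3 alone; camera adjusted p = 0.0123, p = 0.249 with estimated correlation). Immediate-early genes also did (5 of 28 higher and 14 lower, 7 and 14 alone; camera adjusted p = 0.000308, p = 0.156 with estimated correlation). More positive effects were found for cholesterol synthesis genes (25 of 29 higher and 0 lower, 25 and 0 alone; camera adjusted p = 4.68e-11, p = 0.0627 with estimated correlation). Interferon-stimulated genes had 20 of 33 higher and 0 lower (21 and 0 alone; camera adjusted p = 1.02e-05, p = 0.173 with estimated correlation). Histones had 15 of 23 higher and 0 lower (16 and 0 alone; camera adjusted p = 2.23e-05, p = 0.102 with estimated correlation). Mitochondrially encoded transcripts had 12 of 13 higher and 0 lower (12 and 0 alone; camera adjusted p = 3.38e-06, p = 0.249 with estimated correlation). G2/M genes had 18 of 38 higher and 1 lower (18 and 2 alone; camera adjusted p = 0.000424, p = 0.422 with estimated correlation). NRF2 targets had 11 of 29 higher and 5 lower (14 and 5 alone; camera adjusted p = 0.031, p = 0.346 with estimated correlation). In vehicle, cholesterol synthesis genes were lower and ribosomal proteins higher in shZDHHC8 cells, and under cisplatin neither list passed between the backgrounds. Cholesterol synthesis genes then had 13 of 29 higher and 8 lower (15 and 8 alone), with a median of 0.15 (camera adjusted p = 0.438, p = 0.603 with estimated correlation). Ribosomal proteins had 18 of 68 higher and 11 lower (17 and 9 alone), with a median of 0.065 (camera adjusted p = 0.589, p = 0.947 with estimated correlation). The WNT target list did not pass, with 5 of 23 higher and 7 lower (5 and 10 alone), a median of -0.22 and a mean near 0 (camera adjusted p = 0.196, p = 0.324 with estimated correlation). CCND1 rose with cisplatin in shControl cells and fell in shZDHHC8 cells, from 90.2 ± 1.01 to 75.5 ± 0.389 FPKM, an interaction of -1.42 ± 0.058 (SE) (limma adjusted p = 8.31e-06). CTNNB1 had an interaction of 0.34 (limma adjusted p = 0.00676). The interaction of ZDHHC8 itself was 0.43 (limma adjusted p = 0.111), with 0.68 without shZDHHC8 vehicle replicate 1 (adjusted p = 0.00191) and 0.18 without replicate 2 (adjusted p = 0.128).

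**Figure D2:**
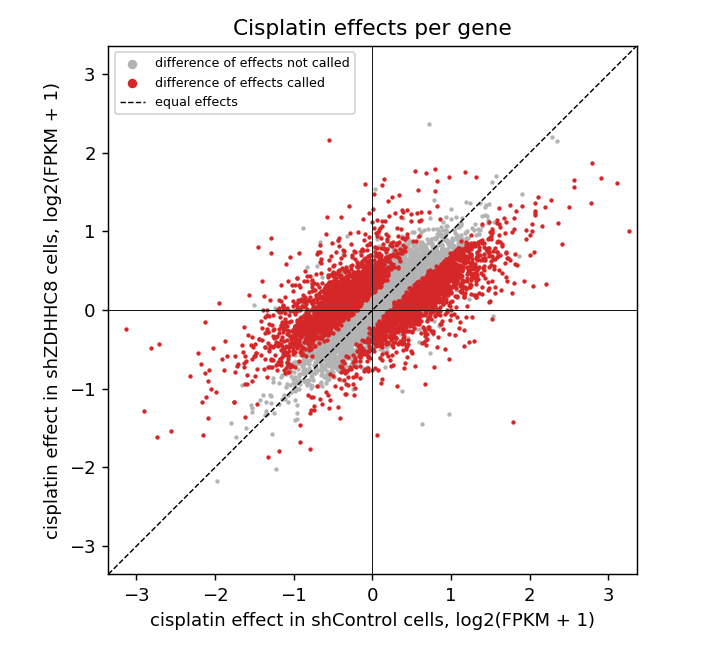
Log2 change with cisplatin of each tested gene in shControl (x axis) and shZDHHC8 cells (y axis), both on the log2(FPKM + 1) scale. Red points are the 4104 genes whose effects differed in the interaction test, grey points the rest, and the dashed line marks equal effects. The SD over genes was 0.51 on the x axis and 0.35 on the y axis.

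The cisplatin effects in both backgrounds share no library. Across the 13495 genes, which are not independent replicates, Pearson's r between them was 0.66 and Spearman's rho 0.65. Of the called genes 3426 were higher in both (1831 if the calls were independent), 1358 lower in both (467 if independent) and 390 opposite. The knockdown effects with vehicle and with cisplatin, which also share no library, had r of 0.67 and rho of 0.64 across genes. Here 2506 genes were higher in both (1217 if independent), 2178 lower in both (930 if independent) and 492 opposite.

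**Figure D3:**
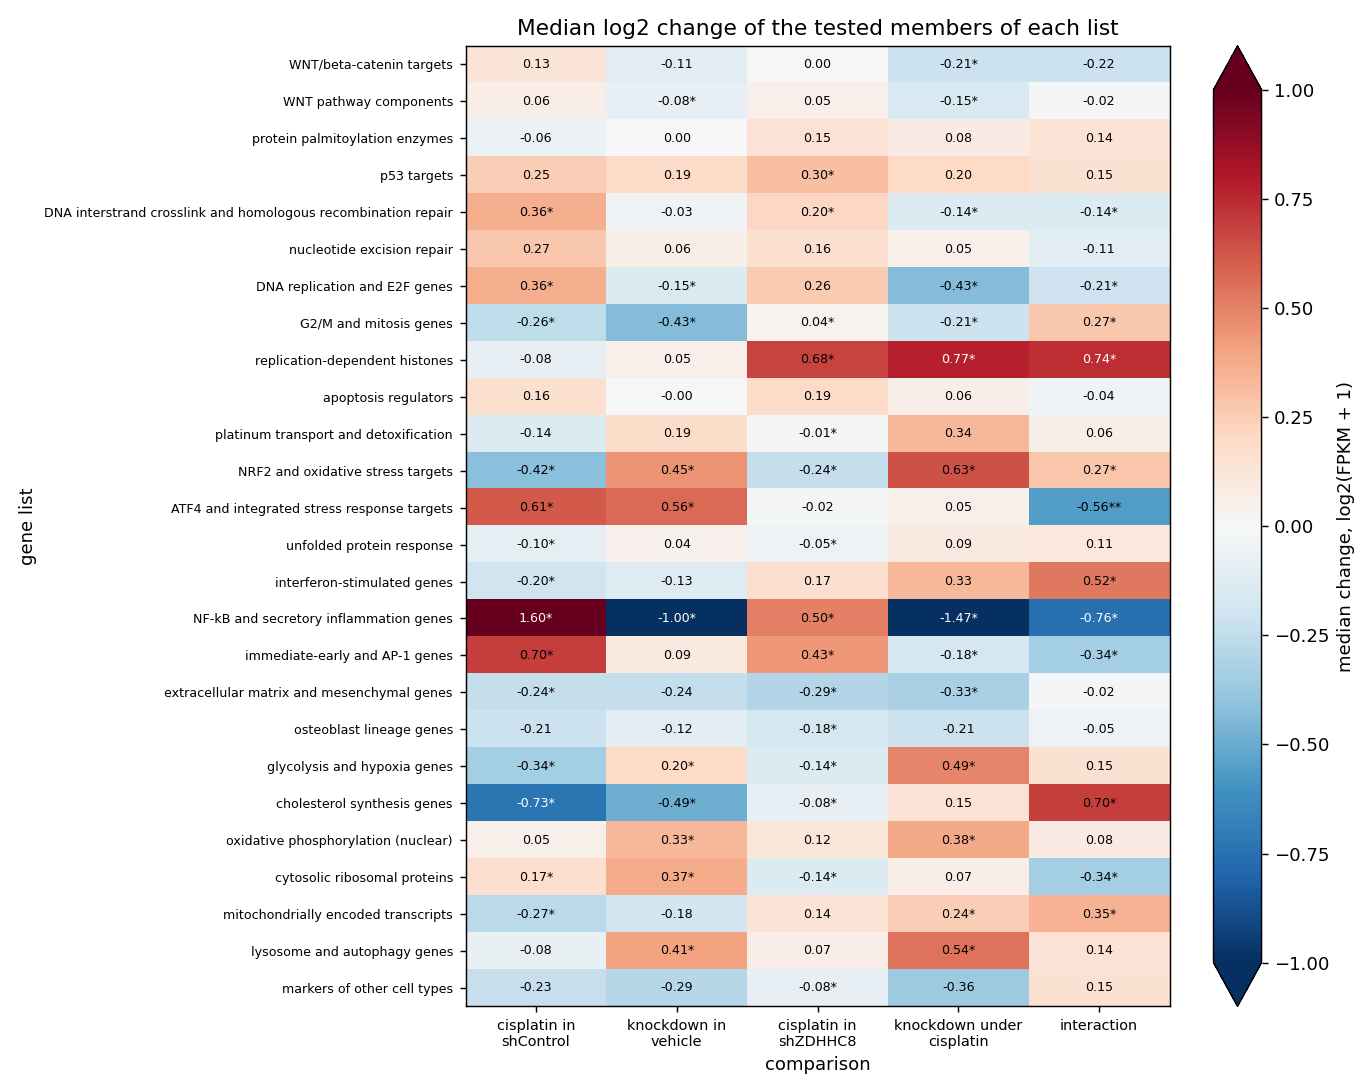
Median log2 change of the tested members of each of the 26 gene lists (rows) in the 5 comparisons (columns), on the log2(FPKM + 1) scale, with red for higher and blue for lower. A star marks a camera adjusted p below 0.05 with the preset correlation, and a second star one that also passed with an estimated correlation, reached by ATF4 targets in the interaction. For cisplatin in shZDHHC8 cells the medians of G2/M genes, WNT targets, WNT pathway components, palmitoylation enzymes, oxidative phosphorylation, mitochondrially encoded and lysosome genes turned below 0 under median-of-ratios scaling.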

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

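The tests of explanations for the smaller cisplatin response were chosen after the result was seen, while the test of the difference was planned before. The results listed here were picked out because the effect of cisplatin differed between shZDHHC8 and shControl cells in a test of the difference itself, the interaction of limma. It passed for 4104 of 13495 genes. Among the genes named by the rule, the difference was most positive for VAV3 (2.90), SAMD11 (2.34), ELF3 (2.26), FAM47E-STBD1 (2.22), H1-2 (2.02), IDO1 (1.99), ZNF852 (1.78) and PROC (1.76). It was most negative for NDUFC2-KCTD14 (-3.21), CCL20 (-2.26), ESM1 (-1.87), TRIB3 (-1.74), RNASET2 (-1.65), SNHG8 (-1.64), CASC19 (-1.64) and TNC (-1.61). NDUFC2-KCTD14 and FAM47E-STBD1 are readthrough genes that share a strand with their parent genes, and the call of NDUFC2-KCTD14 ended without any vehicle library, shControl cisplatin replicate 2 or shZDHHC8 cisplatin replicate 1 (limma adjusted p = 0.0603 to 0.126), with -1.88 without the last of these. It also ended with no filter on low values (adjusted p = 0.103) and with eBayes without a trend (adjusted p = 0.0702).

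Of the gene lists, the median difference was negative for crosslink and homologous recombination repair (-0.14), DNA replication and E2F genes (-0.21), ATF4 and integrated stress response targets (-0.56), NF-kB and secretory inflammation genes (-0.76), immediate-early and AP-1 genes (-0.34) and cytosolic ribosomal proteins (-0.34). It was positive for G2/M and mitosis genes (0.27), replication-dependent histones (0.74), NRF2 and oxidative stress targets (0.27), interferon-stimulated genes (0.52), cholesterol synthesis genes (0.70) and mitochondrially encoded transcripts (0.35). Of these lists only that of ATF4 also passed with an estimated correlation (adjusted p = 0.0262).

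The pattern weighed is a smaller cisplatin response in shZDHHC8 cells. With the shControl response of each gene taken from replicates of a given number, so that selection and test share no library, the slope of the shZDHHC8 response was 0.482 and 0.489 of the slope of the remaining shControl replicates in the 2 choices. Noise in the selection predicts a ratio of 1 and is argued against. So is scaling of whole libraries by the authors, since a factor per library cancels from a slope and leaves the ratio at 1. A weaker exposure to the drug that shrank the response of every gene by the same factor predicts a correlation of the responses near 1. The values corrected for noise lay between 0.721 and 0.735, which argues against that form of it. A weaker exposure to which genes respond unequally would lower the correlation too, so these values cannot judge it.

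Part of the pattern fits a shift of the knockdown cells before treatment: the slope of the knockdown effect in vehicle on the shControl cisplatin effect, with no shared library, was 0.202 and 0.219. What remains open is an effect of ZDHHC8 on the drug response, or a lower effective dose for part or all of the difference. Also open are a difference between the 2 cell populations that arose apart from ZDHHC8, and a normalization that acts differently by level, which was not tested. With a single control and a single knockdown population these were not separated here. The effect of ZDHHC8 itself was not tested.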

How the results depend on the processing

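Results for named genes kept their direction and their side of the threshold in most alternatives. Most of these genes were named for a large change or a small p, so their stability was partly set by that choice. It does not carry over to all genes. Under median-of-ratios scaling 4646 of 6817 calls for cisplatin in shZDHHC8 cells stayed in the same direction. In the interaction 3861 of 4104 did. Every list call except that of ATF4 targets in the interaction ended with an estimated correlation. The counts for named genes leave out ZDHHC8, which lost calls in some alternatives and is described separately. Of 384 results for the other named genes, each a gene in a comparison, a pseudocount of 0.1 left 384 as they were and no filter 383. Without a trend in eBayes 381 stayed, with common-total scaling 383 and with median-of-ratios scaling 384. Leaving out each library in turn kept 3047 and ended 25, all of CTNNB1, NDUFC2-KCTD14 or FAN1, the last in the interaction without shZDHHC8 cisplatin replicate 2. Leaving out a library leaves an arm with 1 sample, which is assumed to vary like the other groups. Common-total scaling, median-of-ratios scaling and the filter at 10 FPKM were chosen after the data had been seen.

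A threshold of 1 on the absolute log2 change left 735, 400, 201, 602 and 265 genes (cisplatin in shControl, knockdown in vehicle, cisplatin in shZDHHC8, knockdown under cisplatin, interaction), and a mean of at least 10 FPKM left 4466, 3964, 3754, 4297 and 2525, since both keep fewer genes. With replicate number as a block the counts were 8249, 6724, 6590, 8129 and 3758, against 8388, 6975, 6817, 8281 and 4104. Deviations of the replicates correlated at -0.0515 to 0.0198 between groups, which shows no pairing.

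ZDHHC8 with cisplatin in shControl cells was 0.34 under median-of-ratios scaling (limma adjusted p = 0.0556) and 0.44 to 0.48 with a library left out. With a library left out its knockdown under cisplatin ranged from -0.53 to -0.46, against -0.59 and -0.55 under common-total and median-of-ratios scaling. Its interaction ranged from 0.18 to 0.68 with a library left out, passing without shZDHHC8 vehicle replicate 1. Agreement of the cisplatin effects was r = 0.643 to 0.658 with a library left out and 0.724 at 10 FPKM or more; agreement of the knockdown effects was 0.650 to 0.661 and 0.697. Their spread over single libraries is narrow (SD 0.00529 and 0.00662).

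For the WNT target list fry passed with medians of 0.13 (cisplatin in shControl), -0.11 (knockdown in vehicle) and -0.22 (interaction), and under cisplatin the knockdown median of -0.21 lost its call with an estimated correlation (adjusted p = 0.181). With a library left out the medians were -0.13 to -0.089 for the knockdown in vehicle, -0.21 to -0.16 for the knockdown under cisplatin and -0.27 to -0.15 for the interaction, and common-total scaling gave -0.17, -0.29 and -0.24. In shZDHHC8 cells with cisplatin, fry reversed the direction of the WNT list (median 0.0042), the ATF4 list (-0.016) and the lysosome list (0.067). Unlike camera, fry does not compare members with other genes, but whether this caused the reversals was not tested. Of the other lists, 64 calls ended with an estimated correlation. The only call that held was that of ATF4 targets in the interaction (camera adjusted p = 0.0262 with estimated correlation). With fry, 33 calls were gained. The causes of these changes were not tested either.

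The planned count-based tests, normalizations and filters were not run, as the values are FPKM. Depth is unknown, so what it limits among low genes could not be measured.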

Other observations

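The tests of small nucleolar RNA hosts and of gene span in shControl cells were chosen after the result was seen, and the other tests of gene span before. Host genes of small nucleolar RNAs were among the long non-coding genes that rose with cisplatin in shControl cells. Of 24 tested genes, 23 SNHG genes and GAS5, chosen after their values were seen, 18 were higher and 2 lower, with a median log2 change of 0.90, while in shZDHHC8 cells 14 were higher and 1 lower with a median of 0.38. Their median interaction was -0.55, and 13 of the 24 had a more negative effect in shZDHHC8 cells. The knockdown in vehicle had 13 higher and 1 lower with a median of 0.32, which lies within the middle 95% of matched random sets of long non-coding genes (-0.085 to 0.349). Under cisplatin the knockdown had 6 higher and 14 lower, with a median of -0.39, below the range of 0.023 to 0.563 of such sets. Transcripts of many of these genes are degraded when they are translated, so they rise when translation or nonsense-mediated decay is reduced. ATF4 targets can rise under the same stress. With cisplatin in shZDHHC8 cells, however, ATF4 targets did not rise with the hosts, as 10 of 32 were higher and 14 lower.

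A general rise of long non-coding genes would raise other such genes of like level as much as the hosts' median of 0.898, but the medians of random sets of them, matched on mean level, had a middle 95% of -0.19 to 0.349. Because the hosts were chosen for their rise, this does not measure how far they stand apart. The knockdown under cisplatin and the interaction use the same shControl cisplatin libraries, so that choice tends to lower their medians too. In shZDHHC8 cells the median of 0.382 was just above the limit of 0.355. It is a hypothesis, not tested here, that reduced translation or decay under cisplatin raised these transcripts.

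Long genes fell with cisplatin. Among 892 genes spanning over 200 kb, the median log2 change was -0.16 in shControl cells, with 44.1% called lower, and -0.18 in shZDHHC8 cells, with 44.8% called lower. GMDS, PTPRM, STX8 and LTBP1 are examples. The raw rank correlation with span was -0.205 in shZDHHC8 cells. Given transcript length, GC content and mean level, it was -0.225 as a partial correlation (SD over single-library pairs 0.00979), and at 10 FPKM or more it was -0.140 (SD 0.0292), so that part of it depends on genes of low level. Both lie below the limit of -0.1, the latter narrowly, which argues against transcript length, GC content and low levels as the whole cause in shZDHHC8 cells.

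In shControl cells the raw rank correlation of -0.0954 already lay above that limit, so the controls were compared with 0.5 times that value. The partial correlation was -0.103 (SD 0.00886) and that at 10 FPKM or more -0.0853 (SD 0.0268), below 0.5 times the raw value by 0.0550 (SD 0.00530) and 0.0377 (SD 0.0144), which argues against these explanations as the whole cause there. A trend present in any comparison stays open, since the knockdown in vehicle gave -0.0881 (SD 0.0372), with -0.117 at 10 FPKM or more and -0.029 as a partial correlation. The knockdown under cisplatin gave -0.114, with -0.0828 at 10 FPKM or more and -0.0805 as a partial correlation. Crosslinks that stop RNA polymerase would lower long genes more than short ones, which is a hypothesis that the deposited values could not test.

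Some genes changed in the same direction with the knockdown in vehicle and under cisplatin, which matters because off-target effects of an shRNA would do so. Loss of ZDHHC8, or a lasting difference between the 2 cell populations, would do so too, so the pattern cannot tell these apart. Changes of at least 1 on the log2 scale in the same direction were found for 190 genes, 103 higher and 87 lower, chosen after their values were seen. For 76 of them the size of the change differed between the comparisons in the interaction, as for IDO1 (-3.07 and -1.09) and TM4SF19 (4.13 and 2.76). Among those of nearly equal change, HSP90AB1, a cytosolic HSP90 chaperone, fell from 593 ± 2.14 to 149.9 ± 6.61 FPKM in vehicle and from 477 ± 16.1 to 120.4 ± 0.467 under cisplatin (log2 changes -1.98 and -1.98). PRKACA changed by -1.26 and -1.26, SRC by -1.04 and -1.06, and CLDN4 by 1.64 and 1.63. ZDHHC8 itself changed by -0.92 and -0.49. A single shRNA is compared with its control, and off-target effects were not tested.

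Levels of some lineage genes, chosen after their values were seen, are given as values. In shControl cells with vehicle ERBB2 was at 1205 FPKM, KRT8 at 649, KRT7 at 362, PAX8 at 208, KRT18 at 168, KRT19 at 115 and SOX17 at 23.1. In the same libraries VIM was at 1761, RUNX2 at 12.9 and SPP1 at 142. COL1A1 was at 5.08, SPARC, of the extracellular matrix list, at 4.74, COL1A2 at 0.826 and COL3A1 at 0.643. CDH2 was at 21.2, EPCAM at 6.39, CDH1 at 0.344, IBSP at 0.332 and BGLAP at 0.138. Keratins and PAX8 are usually epithelial markers, and COL1A1, COL1A2, IBSP and BGLAP, which osteoblasts express, were low here. These levels sit poorly with the label of an osteosarcoma line. The mesenchymal genes VIM and CDH2, the osteoblast lineage genes RUNX2 and SPP1, and the low epithelial genes CDH1 and EPCAM go the other way. The levels were not compared with a reference for 143B cells, and the identity of the cells stays open.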
